A study of Mus musculus with 6 samples.

How the data were processed

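Total RNA of splenic CD8+ T cells was sequenced in 6 mouse libraries. Per the labels' protocols, the cells were isolated from spleen suspensions with a CD8+ T cell isolation kit, ribosomal RNA was depleted, and libraries were built with an Illumina kit. The deposited values are FPKM in 1 table of 14750 genes: a column's values, multiplied by the length of the union of a gene's exons in GENCODE vM21 (GRCm38), were whole multiples of a constant for that library, within a tolerance of 0.1 fragments, for 94.3% to 94.6% of values above 0, and 13716 genes (93.0%) were whole in all 6 libraries. The unit was read from these values, and FPKM and RPKM cannot be told apart because the sources used here do not say whether reads were paired. The larger group mean of every gene in the table was at least 0.5 FPKM, so genes low in both groups are missing from it. The submitters' processing notes list limma, with no version or role. The aligner, the counter and the genome build were not given in the sources used here. Columns summed to between 303278 and 310408 FPKM, and 256 to 383 genes per library were listed at 0.

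Groups were taken from the label that names donor and host strain: 3 libraries labelled allo-HSCT and 3 labelled syn-HSCT. The fragment totals recovered from the FPKM values were 15154000 to 18715000, and the value of 1 fragment per kilobase was 0.0534 to 0.066 FPKM. Every pair of libraries of a group differed beyond counting noise: the median of the squared difference over its counting expectation was 2.41 for genes of 20 to 200 fragments, 2.41 for 200 to 1000 and 2.38 for 1000 to 5000, and 2.62 to 3.76 across pairs for 5000 or more. Each library was counted as a replicate as numbered in the labels; technical spread would also give such ratios, which do not show that the libraries came from separate animals. Intervals from counting alone would be too narrow because of this spread, and errors are SDs or SEs across libraries.

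Genes with at least 1 FPKM in at least 3 of 6 libraries were tested (12404 genes). Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), without covariates, and Benjamini-Hochberg adjusted p under 0.05 was called. Log2 differences are on the log2(FPKM + 1) scale and understate the change of low genes; folds are ratios of mean FPKM. The plan had been written for either counts or normalized values, and the branch for normalized values was used. Gene lists were tested with limma's camera with a preset correlation of 0.01, for lists with at least 5 tested genes, and p was adjusted over the 19 biology lists, or among the lists of other cell types, technical signs and strain genes. Per-gene p-values were also adjusted over each list alone. The lists, the tests across genes and lists, the alternatives except those named as added, and the rule for named genes were fixed before the data were examined, while the comparison of deleted with other beta segments and most tests of explanations were chosen after values had been seen.

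The genes named are the 10 largest gains and the 10 largest losses among called genes with a group mean of at least 5 FPKM and no overlap between groups, without predicted models, immunoglobulin and T cell receptor segments, small RNAs and pseudogenes; 16 preset T cell genes; the strain genes; and up to 4 members of each list with the smallest p. Of these, 1 preset gene and some list members are not reported here. Others (among them B2m, Cd86, Eomes and Stat4 beside lists, members named because they were not called or went against their list, marker genes of other cells, and T cell receptor constant genes) were chosen after their values were seen. Of the gene identifiers, 14730 matched GENCODE vM21 and 20 did not; 9 symbols occurred more than once, and Aldoa is counted as 2 entries of the glycolysis list for that reason. Strain genes serve as a check of the labels.

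Alternatives were leaving out each library in turn, the replicate number as a block, no filter and a filter at 5 FPKM, pseudocounts of 0.1 and 0.01, quantile normalization, TMM factors computed on the values and divided out, eBayes without trend or robust, removal of immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes, an estimated correlation per list, fry, and a 2-fold threshold. Limma's voom on the recovered fragments and limma's treat against 2-fold were added after the data were seen.

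The fit was tested on simulated data with the real means and depths, in which 200 genes were changed. Of the 49, 48, 49 and 47 that entered the fit, 30.6% were called at 1.25-fold and 56.2% at 1.5-fold. At 2-fold 71.4% and at 4-fold 91.5% were called. Among 11193 genes tested, 8 unchanged genes were called, which is 6.2% of the simulated calls. Far more genes were called in the real comparison (67.6%), and the Benjamini-Hochberg cutoff depends on that share. The simulated shares of recovered and false calls therefore do not give those of the real comparison. In simulated lists of 25 genes shifted by 1.5-fold, 10 of 10 were called, and of 10 lists that were not shifted 0 were called by camera. Genes were drawn independently there, so these counts do not give camera's error rate for lists of correlated genes. In the real libraries, splits other than the real one called 3 to 7 lists. Near-identical copies of ribosomal protein genes were found with BLAST+ 2.17.0 at 95% identity or more over at least 40% of the transcript. Permutation tests used scipy 1.17.1 in Python 3.11.15, with 100000 resamples where exact enumeration was not used. With 3 libraries against 3, an exact permutation test between groups cannot give a two-sided p under 0.1, so no such test was run on single genes. Reads were not analysed here.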

Results

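RNA sequencing was used to measure gene expression in splenic CD8+ T cells, the lineage that holds cytotoxic T cells, from mice that had received a hematopoietic stem cell transplantation (HSCT), in which the blood-forming cells of a host are replaced by those of a donor. The series held 6 libraries in 2 groups. The labels gave 3 libraries as syn-HSCT, with BALB/c donor and BALB/c host, and 3 as allo-HSCT, with C57BL/6 donor and BALB/c host. Depth was similar between the groups: the fragment totals recovered from the deposited FPKM values (fragment counts scaled by gene length and library total) were 15310000, 18076000 and 18715000 for replicates 1 to 3 labelled syn-HSCT and 15564000, 16351000 and 15154000 for replicates 1 to 3 labelled allo-HSCT. An FPKM value worth 1 fragment on a gene of 1 kilobase was 0.0534 to 0.066. Across genes, Pearson's r of the log2 values was 0.987 to 0.991 between libraries of a group and 0.867 to 0.873 between groups. Genes are not independent replicates, and these correlations describe the libraries. The labels did not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

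Genes known to differ between the strains were examined first, and their values ran against the labels. H2-Ea-ps, which encodes the MHC class II E alpha chain and is transcribed in BALB/c but not in C57BL/6 mice, reached 1955 FPKM ± 48.9 (SD, n = 3) in the libraries labelled allo-HSCT and 4.76 FPKM ± 1.66 (SD, n = 3) in those labelled syn-HSCT. H2-Eb1, another MHC class II gene, was 28.2-fold higher in the libraries labelled allo-HSCT. Part of the gap may therefore follow the amount of class II transcripts. The ratio of H2-Ea-ps to H2-Eb1 was 1.443 ± 0.012 in the libraries labelled allo-HSCT and 0.098 ± 0.028 in those labelled syn-HSCT (SD, n = 3). Gbp2b, a guanylate-binding protein gene active in BALB/c mice, stood at 22.7 FPKM ± 1.16 (SD, n = 3) against 1.29 FPKM ± 0.193 (SD, n = 3) in the same order. Ly6a, a surface antigen gene that T cells of C57BL/6 mice express more strongly, was 11.6-fold lower in the libraries labelled allo-HSCT (28.6 FPKM ± 1.75 against 332 FPKM ± 0.438, SD, n = 3 each), and Apobec3, a cytidine deaminase gene with a more active C57BL/6 allele, was 5.85-fold lower. Ighg2c, an antibody constant gene of C57BL/6 mice, was at 4.60 FPKM in the libraries labelled allo-HSCT and 32.3 FPKM in those labelled syn-HSCT. The antibody constant genes Ighg1, Ighg2b and Ighg3 were called lower in the same direction and Igha higher, so Ighg2c is not by itself a strain sign. Of the strain lists fixed in advance, 1 of 3 NK or antibody genes of C57BL/6 alone and 2 of 6 genes higher in BALB/c were in the table. Ly6c2 was 3.29-fold lower and its near-identical neighbour Ly6c1 46.8-fold higher in the libraries labelled allo-HSCT, so Ly6c1 went the other way from the rest, and reads of this pair are uncertain. All 7 strain genes named here passed limma's test, with adjusted p from 1.20e-08 for Ly6a to 4.36e-06 for Ighg2c.

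T cells that use certain T cell receptor beta segments are deleted in BALB/c mice by endogenous superantigens, and all 5 such segments measured were lower in the libraries labelled allo-HSCT. Their log2 differences were -2.61 for Trbv16, -2.47 for Trbv12-2, -3.57 for Trbv12-1, -3.29 for Trbv26 and -3.39 for Trbv15. Trbv12-1 and Trbv12-2 are similar in sequence and may share reads. The other 11 beta segments had a median of -0.36, from -1.68 for Trbv29 to 0.61 for Trbv1, and 3 were higher, 6 lower and 2 not called by limma (Trbv4 at -0.19, and Trbv13-2 at -0.06 and at 0.030 after quantile normalization). After quantile normalization Trbv4 was called lower (limma adjusted p = 0.0326, range over 16 settings 0.0326 to 0.702). Trbv14 lost its call after that normalization (limma adjusted p = 0.0544) and without replicate 1, 2 or 3 labelled syn-HSCT (0.0514, 0.0604 and 0.0891), over a range of 0.00342 to 0.0891 in 17 settings. The medians differed by -2.94. A two-sided exact permutation test of the difference of means (-3.065 against -0.292) over the 4368 assignments of segments gave p = 0.00046. All 5 deleted segments lay below every other segment, so this is the smallest p that the test can give. Segments, not animals, were the units, and the test was chosen after the values were seen. As a list the deleted segments were lower by limma's camera test (median -3.29, adjusted p = 0.00151), and with an estimated correlation its adjusted p = 0.143. In GENCODE vM21 annotation of the GRCm38 assembly, H2-Ea-ps is a polymorphic pseudogene on chromosome 17 from 34341959 to 34344645, Gbp2b a protein-coding gene on chromosome 3 from 142594847 to 142619179, and the beta segments lie on chromosome 6 from 40891229 (Trbv1) to 41558452 (Trbv31). Because these genes went against the labels, every direction in the text is one between libraries as labelled, not between kinds of transplant. Donor strain also differed between the groups by design.

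**Figure D1:**
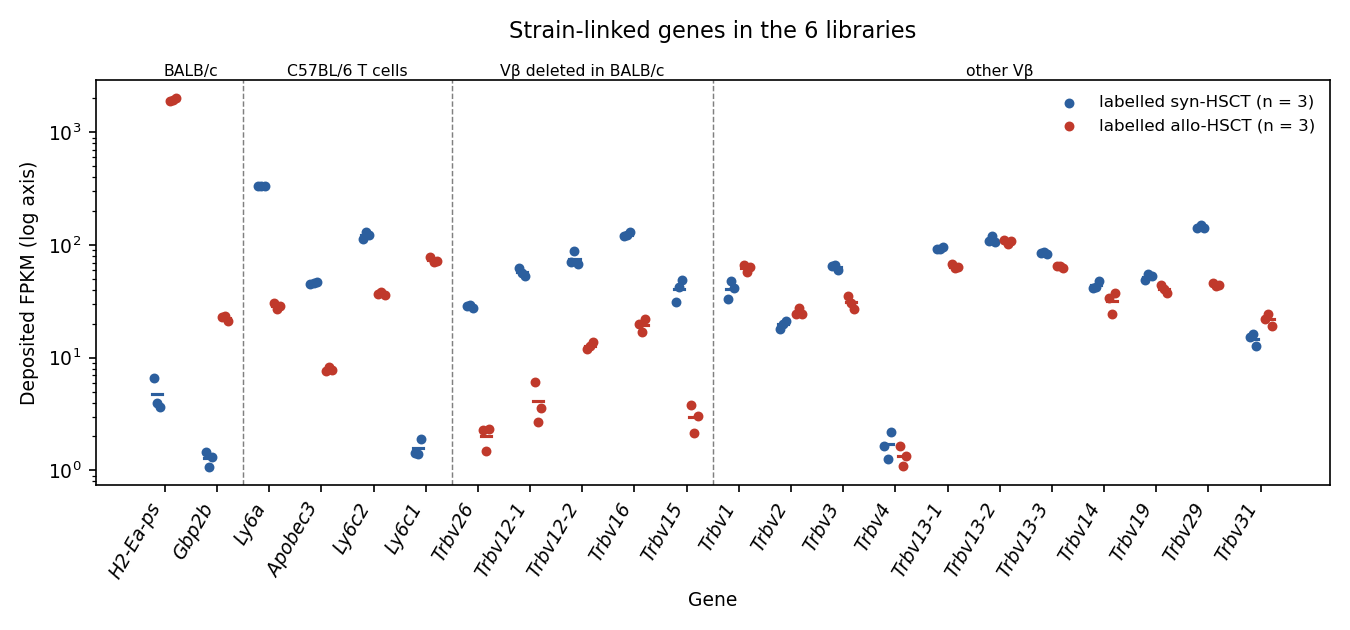
Deposited FPKM (vertical log axis) of strain-linked genes (horizontal axis) in each library; points are libraries, short bars are group means, blue is labelled syn-HSCT and red labelled allo-HSCT (n = 3 each). H2-Ea-ps is at 1955 FPKM in the red group and 4.76 FPKM in the blue group, and all 5 segments deleted in BALB/c are lower in the red group.

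The comparison the design implies asks how CD8+ T cells differ after allogeneic and syngeneic transplantation. In the libraries labelled allo-HSCT, transcripts of antigen-presenting cells were among the largest gains. Cd207, which encodes the lectin langerin of dendritic cells, was at 56.6 FPKM ± 1.48 (SD, n = 3) against 0.0624 FPKM ± 0.0406 (SD, n = 3). The MHC class II genes H2-Eb1 and Cd74, the latter encoding the invariant chain, were 28.2-fold and 25.8-fold higher, at 1355 FPKM ± 25.6 and 2568 FPKM ± 81.3 (SD, n = 3). Pdcd1, which encodes the inhibitory receptor PD-1, was 29.8-fold lower, at 7.73 FPKM ± 0.602 against 231 FPKM ± 4.78 (SD, n = 3). Gzmc, which encodes granzyme C, was at 0.623 FPKM ± 0.367 against 25.6 FPKM ± 2.69 (SD, n = 3), with reads that it may share with neighbouring granzyme genes of similar sequence.

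By limma, 4298 of the 12404 genes tested were higher and 4092 lower in the libraries labelled allo-HSCT, and 4014 were not called. The balance turned after quantile normalization (3742 higher and 4790 lower), after TMM scaling (3970 and 4483), without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes (4150 and 4235) and among genes of at least 5 FPKM (2817 and 3248). The groups did not overlap at 8964 genes, which is 72.3% of those tested, where chance gives 10%. At 2-fold or more, 1264 called genes were higher and 611 lower, so 67.4% of them were higher; after quantile normalization the split was 981 to 790, with 55.4% higher. The 10 largest gains on the log2(FPKM + 1) scale, which understates changes of low genes, were Cd207 (5.76 ± 0.05, SE), Tifab (5.31), Plbd1 (5.07), Rtl8c (4.95), Ly6c1 (4.87), Mpeg1 (4.84), H2-Eb1 (4.79), Wdfy4 (4.75), Cd74 (4.68) and H2-DMb2 (4.67). Mpeg1 encodes a pore-forming protein of macrophages, Wdfy4 acts in cross-presentation by dendritic cells, and H2-DMb2 takes part in loading peptides on MHC class II. The 10 largest losses were Rpl29 (-6.19 ± 0.12, SE), Pdcd1 (-4.73), Rps2 (-4.72), Baiap3 (-4.29), Gzmc (-4.05), Gldc (-3.80), Klrb1b (-3.77), Trim12a (-3.62), Oas1a (-3.57) and Ly6a (-3.49). Gldc encodes the decarboxylase of the glycine cleavage system, Klrb1b a lectin-like receptor of NK cells, and Oas1a an oligoadenylate synthetase induced by interferon. Klrb1b, Trim12a and Oas1a were all under 0.04 FPKM as group means in the libraries labelled allo-HSCT (0.0195, 0.026 and 0.023), against 13.0, 11.7 and 11.2 FPKM. Rpl29 and Rps2, which encode ribosomal proteins, have near-identical processed copies in the genome, and Trim12a and Oas1a have close paralogs, so their values are uncertain. These 20 genes had limma adjusted p of at most 1.64e-06.

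In the list of inhibitory receptors and exhaustion, more genes were lower than higher in the libraries labelled allo-HSCT. Of 24 measured genes, 16 fell, 7 rose and 1 (Nr4a3) was not called; adjusted over the list alone, 16 fell and 8 rose. Beside Pdcd1, Tigit fell from 242 to 29.7 FPKM and Ctla4 from 60.1 to 5.72 FPKM, both encoding receptors that restrain T cells. Havcr2, which encodes TIM-3, was at 39.6 FPKM ± 1.11 against 119 FPKM ± 2.50 (SD, n = 3), and Lag3 was 7.47-fold lower. Tox, a transcription factor gene of exhausted T cells, was 3.84-fold lower, at 2.56 against 9.84 FPKM. The 7 that rose were Eomes, Btla, Nr4a1, Cd38, Entpd1, Lgals9 and Cd101; Eomes, a T-box factor gene of memory and exhausted cells, rose from 12.9 to 39.8 FPKM. The list median was -0.87 (limma's camera, adjusted p = 0.0112). With an estimated correlation camera's adjusted p = 0.101, and with genes of at least 5 FPKM alone it was 0.0776 (range over 19 settings 0.0051 to 0.101). The dendritic cell list rose beside it, with a median of 3.65 (camera adjusted p = 0.0906 with an estimated correlation).

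Genes of activation and of cytotoxic function went down in larger number than up. Of 25 genes of activation and costimulation, 16 fell, 8 rose and 1 (Cd44) was not called, with the same counts adjusted over the list alone. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, fell from 52.8 to 7.53 FPKM, Icos from 47.0 to 12.3 FPKM, and Il2ra, the alpha chain of the interleukin 2 receptor, from 27.0 to 3.25 FPKM. Il2rb, which encodes the beta chain, was 2.23-fold lower. Cd83, a gene of mature dendritic cells and activated lymphocytes, rose from 0.502 to 13.6 FPKM, and Cd86, which encodes a ligand on antigen-presenting cells, also rose. The list median was -0.65 (limma's camera, adjusted p = 0.0367), and with an estimated correlation camera's adjusted p = 0.140. That call was also lost after quantile normalization (camera adjusted p = 0.129), TMM scaling (0.0513) and a fit to recovered fragments (0.102), over a range of 0.0206 to 0.140 in 19 settings. Of 26 cytotoxic effector genes, 17 fell, 7 rose and 2 (Id2 and Tnfsf10) were not called, and the counts were the same adjusted over the list alone. Gzmb, which encodes granzyme B, was at 465 FPKM ± 15.1 against 2029 FPKM ± 41.1 (SD, n = 3), and Prf1, which encodes perforin, at 66.9 FPKM ± 1.22 against 244 FPKM ± 3.71 (SD, n = 3). Ifng, the gene of interferon gamma, was 1.96-fold lower and Tbx21, the gene of the effector transcription factor T-bet, 1.66-fold lower. Ccl5, a chemokine gene of effector and memory cells, was 3.59-fold higher, at 1214 FPKM ± 50.03 against 338 FPKM ± 10.6 (SD, n = 3), and S1pr5, which encodes a receptor for exit from tissue, rose from 2.04 to 25.1 FPKM. The cytotoxic list had a median of -0.33 (limma's camera, adjusted p = 0.0367). Its call was lost with an estimated correlation (camera adjusted p = 0.368) and after quantile normalization (0.185), over a range of 0.0107 to 0.368. T cell receptor constant and CD3 genes were lower beside these lists, at -0.68 for Trac, -0.69 for Trbc1 and -0.16 for Cd3e on the log2 scale, and Cd8b1 was at 490 against 483 FPKM and not called. The dendritic cell and neutrophil lists rose beside them, with medians of 3.65 and 3.32, as did the list of immediate-early and dissociation genes, with a median of 1.013 and 16 of 21 genes higher. With an estimated correlation camera's adjusted p = 0.0906 for the dendritic cell list, 0.0358 for the neutrophil list and 0.0906 for the immediate-early list.

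In the naive, memory and quiescence list, 18 of 24 measured genes were higher in the libraries labelled allo-HSCT. Tcf7, which encodes the transcription factor TCF-1, was 7.18-fold higher, at 117 FPKM ± 1.78 against 16.3 FPKM ± 0.31 (SD, n = 3). Ccr7, a chemokine receptor gene for entry to lymph nodes, was at 29.1 FPKM ± 2.84 against 1.28 FPKM ± 0.387 (SD, n = 3). Il7r, which encodes the interleukin 7 receptor, was 1.32-fold higher. Of 24 measured genes of the naive, memory and quiescence list, 18 rose, 3 (Ly6c2, S1pr1 and Ets1) fell and 3 (Slamf6, Lef1 and Klf2) were not called, as they were adjusted over the list alone. Btg1, an antiproliferative gene, rose from 36.5 to 117 FPKM, and Klf3 from 9.03 to 23.2 FPKM. The list median was 0.82 (limma's camera, adjusted p = 0.000258), and with an estimated correlation camera's adjusted p = 0.0512 (range over 19 settings 1.42e-05 to 0.0512). Dendritic cells also express Ccr7, and their list rose with a median of 3.65 (camera adjusted p = 0.0906 with an estimated correlation).

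**Figure D2:**
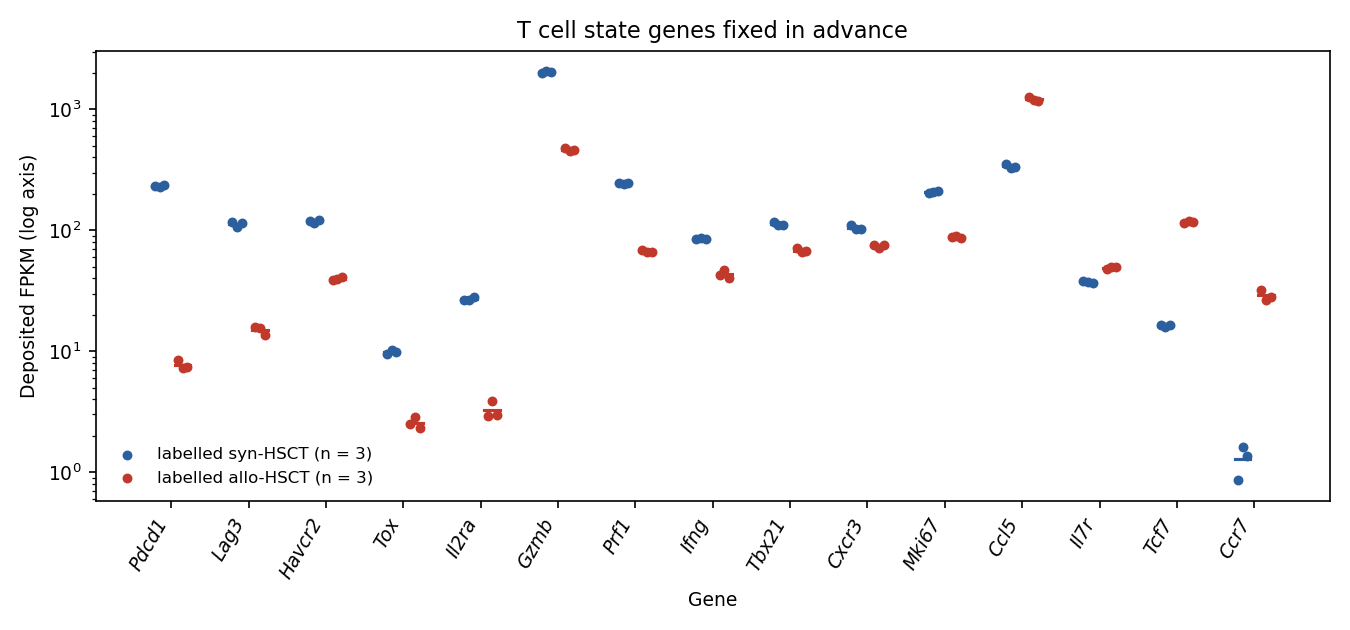
Deposited FPKM (vertical log axis) of 15 T cell genes fixed in advance (horizontal axis) in each library; points are libraries, short bars are group means, blue is labelled syn-HSCT and red labelled allo-HSCT (n = 3 each). Pdcd1 is at 231 FPKM in the blue group and 7.73 FPKM in the red group, and Tcf7 at 16.3 and 117 FPKM.

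Cell cycle genes fell together. Of 40 measured, 39 fell, 0 rose and 1 (E2f1, at 12.8 against 13.4 FPKM) was not called, and the counts were the same adjusted over the list alone. Mki67, which encodes the proliferation marker Ki-67, was at 88.1 FPKM ± 0.975 in the libraries labelled allo-HSCT and 206 FPKM ± 3.496 (SD, n = 3) in those labelled syn-HSCT. Ccnb1, which encodes the mitotic cyclin B, fell from 44.3 to 11.9 FPKM, Tpx2, a spindle assembly gene, from 61.3 to 22.3 FPKM, and Cenpe, a kinetochore motor gene, from 32.3 to 10.9 FPKM. The median was -1.11 (limma's camera, adjusted p = 7.47e-16), and with an estimated correlation camera's adjusted p = 0.0510 (range over 19 settings 5.56e-21 to 0.0510). The neutrophil list rose beside them, with a median of 3.32 (camera adjusted p = 0.0358 with an estimated correlation).

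Genes of energy metabolism were lower on balance. Of 31 nuclear genes of oxidative phosphorylation, 28 fell, 0 rose and 3 (Ndufa2, Ndufs7 and Ndufa4) were not called, the same as adjusted over the list alone, with a median of -0.28 (limma's camera, adjusted p = 1.96e-05). With an estimated correlation camera's adjusted p = 0.0512 (range over 19 settings 6.80e-06 to 0.0512). Ndufb9, a subunit gene of complex I, fell from 21.7 to 11.7 FPKM, Sdhb, of succinate dehydrogenase, from 55.4 to 37.9 FPKM, and Atp5b, of ATP synthase, from 233 to 191 FPKM. Of 19 fatty acid oxidation genes, 15 fell, 3 rose and 1 (Hadhb) was not called, and adjusted over the list alone 16 fell. Acadl, an acyl-CoA dehydrogenase gene, fell from 77.6 to 44.2 FPKM and Cpt1a, which encodes the carnitine transferase at the mitochondrial membrane, from 58.7 to 38.4 FPKM. Cd36, a fatty acid uptake gene also used by macrophages, rose from 1.77 to 27.5 FPKM. The fatty acid list had a median of -0.38 (limma's camera, adjusted p = 0.015). It was not called with an estimated correlation (camera adjusted p = 0.140) or in a fit to recovered fragments (0.0626), over a range of 0.00785 to 0.140. Of 24 glycolysis entries, 15 fell, 7 rose and 2 (Gpi1 and Gapdh) were not called, with the same counts adjusted over the list alone. Tpi1, a triose isomerase gene, fell from 89.9 to 39.9 FPKM, Ldha, of lactate dehydrogenase, from 308 to 190 FPKM, and Hif1a, a hypoxia factor gene, from 52.0 to 22.5 FPKM. Eno1 fell from 179 to 55.4 FPKM while its near-identical copy Eno1b rose from 13.0 to 56.0 FPKM, so reads of this pair are uncertain, as are those of Gapdh, which has many processed copies and was listed at 6.89 FPKM ± 0.391 against 8.96 FPKM ± 7.08 (SD, n = 3). The glycolysis list had a median of -0.30 (limma's camera, adjusted p = 0.037), and with an estimated correlation camera's adjusted p = 0.227. Its call was also lost after quantile normalization (camera adjusted p = 0.151), after TMM scaling (0.0513) and without replicate 1 labelled syn-HSCT (0.0791), over a range of 0.00134 to 0.227. The macrophage list rose beside these lists, with a median of 1.46 (camera adjusted p = 0.0597 with an estimated correlation). T cell receptor constant and CD3 genes were lower too, from -0.16 for Cd3e to -0.74 for Cd3g on the log2 scale. The medians of the metabolic lists lie within that range, while Cd8a was called higher and Cd8b1 not called. Whether the share of T cells lowered the metabolic lists was not tested.

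Most interferon response genes were higher in the libraries labelled allo-HSCT. Of 31 genes of the type I interferon response, 27 rose, 2 (Oas1a and Ifih1) fell and 2 (Isg20 and Cmpk2) were not called, the same as adjusted over the list alone. Irf7, the factor that amplifies interferon production, rose from 14.2 to 44.0 FPKM, Oasl1 from 0.762 to 7.65 FPKM, and Ifi44 was at 6.13 against 0.132 FPKM. The median was 0.86 (limma's camera, adjusted p = 1.42e-05), and with an estimated correlation camera's adjusted p = 0.0510 (range over 19 settings 1.47e-06 to 0.0510). Of 28 genes of the interferon gamma response and antigen presentation, 21 rose, 1 (Gbp3) fell and 6 were not called, and adjusted over the list alone 22 rose. Ciita, the transactivator of MHC class II, rose from 0.866 to 33.5 FPKM, Irf8, a factor of dendritic cell development, from 20.5 to 162 FPKM, and Cxcl9, a chemokine gene induced by interferon gamma, from 1.60 to 36.7 FPKM. These 3 are also expressed by antigen-presenting cells. B2m, which encodes the light chain of MHC class I, was at 2140.4 against 2130.0 FPKM and not called. This list had a median of 0.30 (limma's camera, adjusted p = 0.00027), and with an estimated correlation camera's adjusted p = 0.0512 (range over 19 settings 1.34e-05 to 0.0512). Beside both lists, all 15 dendritic cell genes rose, with a median of 3.65 (camera adjusted p of the list = 0.0906 with an estimated correlation).

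JAK-STAT genes rose more often than they fell. Of 22 measured, 15 rose, 6 fell and 1 (Socs6) was not called, the same as adjusted over the list alone. Pim2, a survival kinase gene, rose from 15.4 to 28.1 FPKM and Jak1 from 104 to 148 FPKM, and Stat4, which acts in the response to interleukin 12, fell from 30.1 to 18.3 FPKM. The median was 0.36 (limma's camera, adjusted p = 0.037), and with an estimated correlation camera's adjusted p = 0.140 (range over 19 settings 0.0177 to 0.140). The dendritic cell and neutrophil lists rose beside it, with medians of 3.65 and 3.32 (camera adjusted p = 0.0906 and 0.0358 with an estimated correlation). None of the 11 list calls held with an estimated correlation in limma's camera, where 6 of 19 lists had an unadjusted p under 0.05, while fry called all 19 lists, 8 higher and 11 lower.

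The remaining 8 lists were not called by limma's camera, although most of their members were called one by one. Of 20 cholesterol synthesis genes 6 rose and 12 fell (camera adjusted p = 0.0802), and of 23 genes of the unfolded protein response 5 rose and 14 fell (camera adjusted p = 0.0802; 0.0345 in a fit to recovered fragments, with a range of 0.0345 to 0.811). Atf3, a stress-induced factor gene, rose from 0.492 to 20.8 FPKM. Of 23 genes of chemokine receptors and homing 9 rose and 12 fell (camera adjusted p = 0.679); Itgae, which encodes the integrin chain CD103 of tissue-resident T cells and some dendritic cells, rose from 3.49 to 36.4 FPKM, Itgb7 fell from 372 to 188 FPKM, Cxcr6 fell from 133 to 68.4 FPKM, and Cxcr3, a receptor gene of effector T cells, was 1.41-fold lower. Its median (-0.17) and its mean (0.35) differed in sign. Of 27 genes of cytokines and their receptors 13 rose and 13 fell (camera adjusted p = 0.689), with a median of 0.03 and a mean of -0.22; Il18r1, an interleukin 18 receptor gene, fell from 143 to 46.8 FPKM, Il1rl1 fell from 10.99 to 0.617 FPKM, and Ltb, the gene of lymphotoxin beta, rose from 62.9 to 197 FPKM. Of 30 T cell receptor signalling genes 14 rose and 11 fell (camera adjusted p = 0.809), among them Ptpn22, which fell from 73.6 to 44.1 FPKM. Of 28 apoptosis genes 11 rose and 11 fell (camera adjusted p = 0.967); the median was -0.001 and the mean 0.12. Of 30 genes of ribosome biogenesis 11 rose and 8 fell (camera adjusted p = 0.735). Of 40 ribosomal protein genes 18 rose, 12 fell and 10 were not called (camera adjusted p = 0.735), with a median of 0.07, of -0.01 after quantile normalization, and a mean of -0.19. Adjusted over the list alone, 12 apoptosis genes fell, and the counts of the other 7 lists were the same. With an estimated correlation the lowest camera adjusted p of these lists was 0.193. The dendritic cell list rose beside them, with a median of 3.65 (camera adjusted p = 0.0906 with an estimated correlation).

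Markers of other cell types moved with the groups. All 15 dendritic cell genes were higher in the libraries labelled allo-HSCT (median 3.65; limma's camera, adjusted p = 9.05e-09; adjusted p = 0.0906 with an estimated correlation), and their FPKM summed to 6161 against 347. The MHC class II genes Cd74 (2568 FPKM) and H2-Eb1 (1355 FPKM) made up most of the larger sum, so it mainly follows class II transcripts. Clec9a and Xcr1, genes of cross-presenting dendritic cells, rose from 2.29 to 65.4 and from 3.89 to 60.4 FPKM, and Flt3 rose from 0.784 to 22.6 FPKM. Of 19 neutrophil and myeloid precursor genes 18 were higher and 1 (Elane) was not called (median 3.32; camera adjusted p = 9.05e-09; adjusted p = 0.0358 with an estimated correlation), with S100a9, a calcium-binding protein gene of neutrophils, at 851 against 41.1 FPKM. Of 22 monocyte and macrophage genes 20 were higher, 1 (Ly6c2) lower and 1 (Axl) not called (median 1.46; camera adjusted p = 5.74e-07; adjusted p = 0.0597 with an estimated correlation), with Lyz2, a lysozyme gene, at 242 against 12.3 FPKM. Erythroid genes (8 of 10 higher, median 1.83, camera adjusted p = 0.00151), mast cell, basophil and eosinophil genes (4 of 5 higher, median 1.71, camera adjusted p = 0.00892) and B cell genes (5 of 7 higher, median 0.84, camera adjusted p = 0.0106) were also higher, and each of these 3 had an adjusted p = 0.0906 with an estimated correlation. Genes of CD4 T cells (2 higher, 6 lower, camera adjusted p = 0.0949), plasma cells (3 higher, 7 lower, camera adjusted p = 0.112) and NK cells (5 higher, 5 lower, camera adjusted p = 0.678) were not called as lists. The CD4 list was called lower in a fit to recovered fragments (camera adjusted p = 0.0238, range over 17 settings 0.0238 to 0.131). With fewer than 5 genes past the filter and so no list test with that filter, 2 of 4 gamma delta T cell genes were higher and 1 lower, 3 of 3 megakaryocyte genes were higher, and of 2 stromal genes 1 was higher and 1 lower. Without the filter, limma's camera called the megakaryocyte list higher (adjusted p = 0.0102). It did not call the gamma delta T cell list (camera adjusted p = 0.481) or the stromal list (0.1045).

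Genes induced by handling and stress of cells also moved. Of 21 immediate-early and dissociation genes 16 were higher and 3 lower in the libraries labelled allo-HSCT (median 1.013; limma's camera, adjusted p = 0.00015; adjusted p = 0.0906 with an estimated correlation). Fos, an early response gene, rose from 21.2 to 139 FPKM and Junb from 77.4 to 164 FPKM. Of 13 mitochondrial genes 5 were higher, 2 lower and 6 not called (median 0.05, -0.04 after quantile normalization, and mean -0.09; camera adjusted p = 0.749). Xist, which marks female cells, was at 80.02 against 81.9 FPKM and not called, and of the 4 Y-linked genes of the list 0 were among the genes tested.

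**Figure D3:**
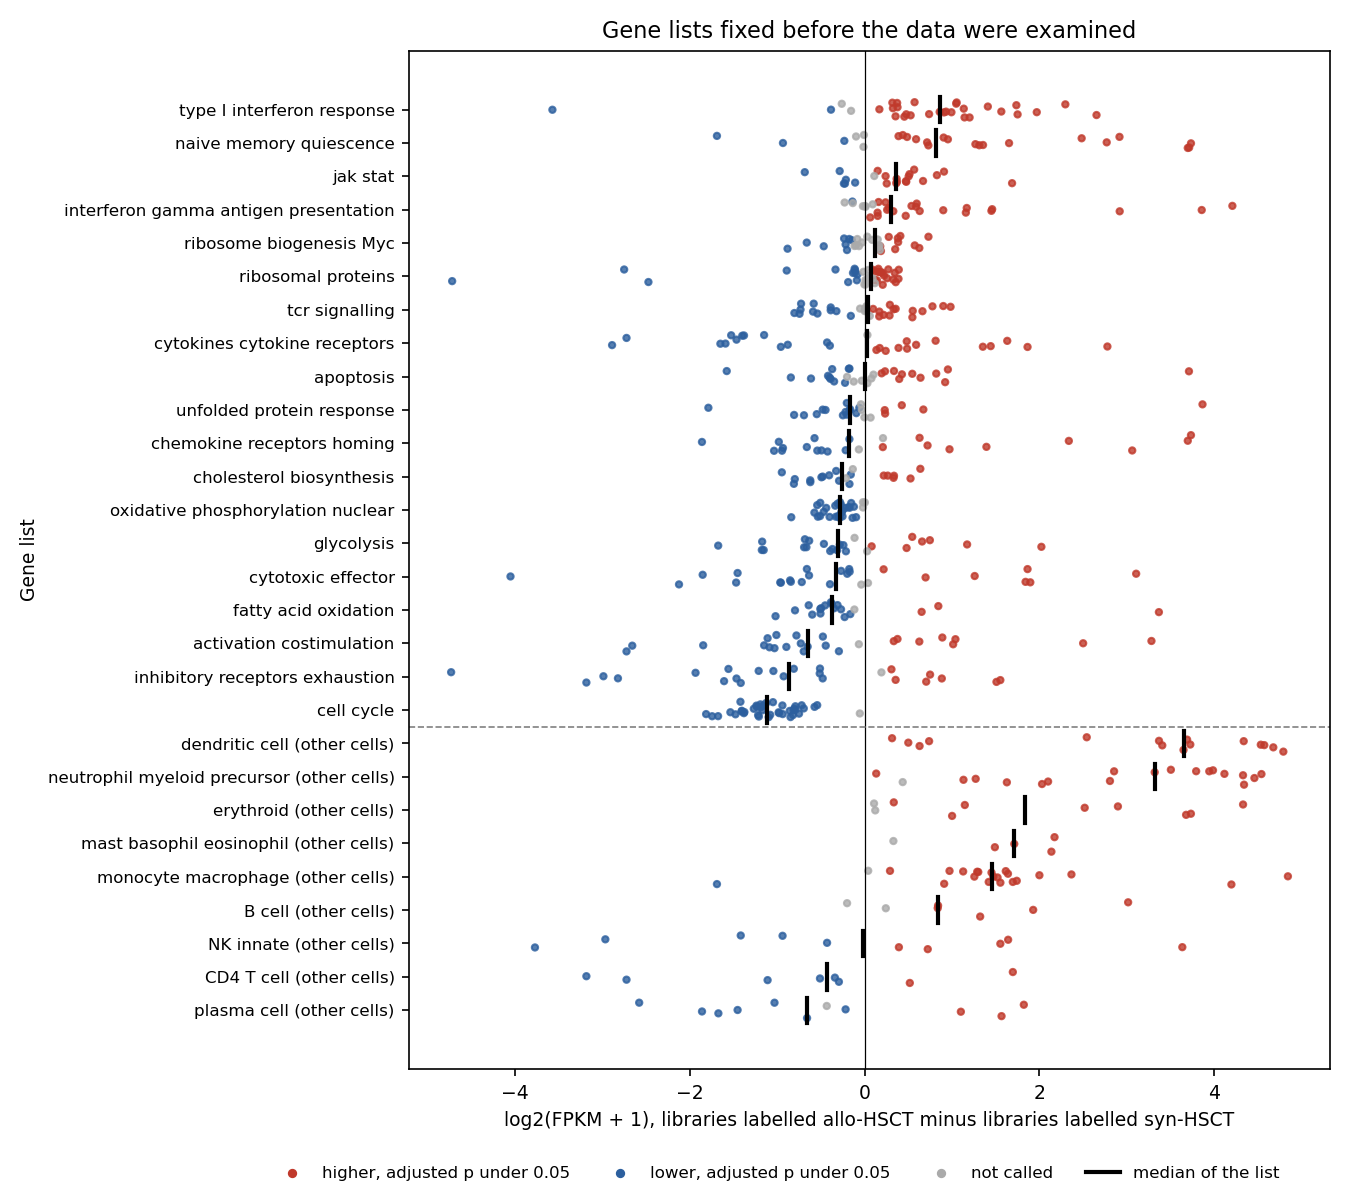
Log2 difference of FPKM + 1, libraries labelled allo-HSCT minus libraries labelled syn-HSCT (horizontal axis), for each tested gene of each list with at least 5 tested genes (vertical axis); red points were called higher, blue points called lower and grey points not called by limma, and black bars are list medians. Below the dashed line are the lists of other cell types. The cell cycle list has a median of -1.11 and the dendritic cell list a median of 3.65.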

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

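The fit to recovered fragments and the test against 2-fold (treat) were chosen after the data were seen. Leaving out 1 library at a time gave 4059 to 4126 genes higher, 3765 to 3890 lower, 4 lists higher in every case and 6 to 7 lists lower. With genes of at least 5 FPKM alone, 2817 genes were higher and 3248 lower of 8075 tested, after quantile normalization 3742 were higher and 4790 lower, with TMM factors 3970 and 4483, and without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes 4150 and 4235, so more genes were lower than higher in these settings; the cause was not tested. With a 2-fold threshold as well, 1264 were higher and 611 lower, and treat called 809 and 351, as their stricter criteria require. After quantile normalization 4 lists were lower; the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower by limma's camera (3 and 3 at an unadjusted p under 0.05), against 8 and 11 by fry, which does not compare a list with other genes. In a test chosen after this was seen, the loss came mostly from the 4 residual degrees of freedom that camera then uses: with estimated correlations but the 12402 degrees of freedom of the preset test 4 lists were higher and 5 lower, without the cytotoxic and glycolysis lists, and with the preset correlation but 4 degrees of freedom 0 were higher and 1, the cell cycle list, lower. The fit to recovered fragments, on 11454 genes, called 4077 higher and 3907 lower, and 7552 of its calls were shared with those reported. Over all alternatives, 922 values of named genes kept direction and side of the threshold, 4 lost the call (all Trbv14), 1 gained it (Trbv4) and 1 reversed; of the values of lists, 326 were the same, 22 lost the call, 6 gained it and 7 reversed. The reversals, whose cause was not tested, were Trbv13-2 after quantile normalization (0.030), the apoptosis list without replicate 3 labelled syn-HSCT (0.037; -0.041 to 0.037 over libraries left out), at 5 FPKM (0.077), after quantile normalization (-0.071) and by fry (-0.00057), ribosomal proteins after quantile normalization (-0.0084) and by fry (0.072), and chemokine receptors by fry (-0.17); the values of lists are medians, and the sign that reversed is that of the test.

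The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.06, 0.12 and -0.08 across genes. With the replicate block 4164 genes were higher and 3949 lower, and 3 lists were higher and 6 lower, as the glycolysis list (camera adjusted p = 0.0626, range over settings 0.00134 to 0.227) and the JAK-STAT list (0.053, range 0.0177 to 0.140) lost their calls. Alternatives planned for count tables were not run, since the values are FPKM. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes (8390, highest other 16) and 1 gave as many lists (11, highest other 7); 10 splits are too few for a share under 0.05.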

Other observations

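The genes in this paragraph were chosen after their values were seen. Gzmd, Gzme and Gzmf, granzyme genes of a cluster beside Gzmb, had values above 0 only in the libraries labelled syn-HSCT. Gzmc, named above among the largest losses, lies in the same cluster and was above 0 in both groups. No test was run on Gzmd, Gzme and Gzmf as a set, Gzmd did not pass the filter, and reads may be shared among these similar neighbours. Gzmf was listed at 0 in all 3 libraries labelled allo-HSCT and at 5.40, 4.21 and 5.76 FPKM in those labelled syn-HSCT, Gzme at 0 against 2.21, 2.11 and 1.34 FPKM, and Gzmd at 0 against 1.49, 0.746 and 1.22 FPKM. Gzma, another granzyme gene, was 1.95-fold lower in the libraries labelled allo-HSCT, and Gzmm, the gene of granzyme M, 4.02-fold higher. Klrb1c, which encodes an NK cell receptor known as NK1.1 in C57BL/6 mice, fell from 11.3 to 0.574 FPKM. The NK cell list to which Klrb1c belongs holds strain variants, and 5 of its genes were higher and 5 lower. Among MHC class I genes, H2-K1 fell from 873.0 to 414 FPKM and H2-Q7 from 181 to 93.2 FPKM, while H2-D1 was at 881 against 873 FPKM and not called by limma; these genes are polymorphic and similar in sequence, so their values are uncertain. Psap, a lysosomal gene, rose from 222 to 1852 FPKM.

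Of the tests that follow, only that of Rpl29 copies was written down before its result was seen; the others were chosen after the patterns were seen. Strain genes ran against the labels. In the libraries labelled syn-HSCT, with BALB/c donor and host, the ratio of H2-Ea-ps to H2-Eb1 was 0.098 ± 0.028 against 1.443 ± 0.012 (SD, n = 3) in those labelled allo-HSCT, which argues against BALB/c host cells in correctly labelled libraries as the source. A lower share of T cells in the libraries labelled allo-HSCT is argued against as the sole source of the fall of the deleted beta segments. The least lowered of them lay -1.72 log2 units from the most lowered T cell receptor constant or CD3 gene, Cd3g (-0.74). Such a lower share is not itself excluded, as the T cell receptor constant and CD3 genes measured were all lower. Libraries with BALB/c donor and host would hold BALB/c cells alone. The ratio and the difference of -2.94 between the medians of deleted and other segments therefore argue against the labels as given. Ly6c1, whose reads are uncertain, went the other way. The sample titles carry the letter A for libraries labelled syn-HSCT and S for those labelled allo-HSCT. Exchanged group labels would give such a difference between segments, so an exchange of the 2 labels is a candidate explanation. If it holds, every direction would turn round, and the libraries with high Pdcd1, Gzmb and cell cycle genes would be the allogeneic ones.

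Genes of dendritic cells, macrophages and neutrophils were higher in the libraries labelled allo-HSCT (53 of 56, median 2.02; 19 of the 56 had at least 5 FPKM in the libraries labelled syn-HSCT as well, and 4 are also in biology lists). Scaling is argued against, as the lowest dendritic cell median over 18 settings was 3.406. For a lower share of T cells that raises all other cells alike, 8 lists of other cells, with 87 genes found in 1 list alone, were compared. Medians of the log2 ratio of FPKM ranged over 5.03 (dendritic 4.63, erythroid 4.53, neutrophil 4.35, mast cell 3.11, macrophage 2.07, B cell 0.84, NK 0.04 and plasma cell -0.40). A rank-based permutation test across the lists, with genes as units, gave p = 1e-05, the smallest that the resamples can give. The same permutation test gave p = 0.012 without the NK and plasma cell lists, which hold strain variants. Unequal medians cannot decide this question, as genes that T cells also express have ratios drawn toward 0. A lower share of T cells behind the gains of dendritic cell and neutrophil genes alone stays open, since their medians lay 0.28 apart and added cells of both types would give the same, and so does a difference in spleen composition between the transplants or strains, which was not tested. Reads from other cells in the isolated fraction stay open as well, since the 53 gains only restate the pattern and within groups the genes of the dendritic cell list moved together (correlation 0.215) but hardly those of the macrophage (0.025, the median of the 3) and neutrophil lists (-0.034), which a steady amount of such cells would also give; the isolation kit is meant to remove them. Cd8a rose relative to Cd8b1 by 0.53 ± 0.04 (SE) on the log2 scale, which is consistent with dendritic cells that carry CD8 alpha without CD8 beta, and would leave neutrophil genes to another source.

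Rps2, Rps18 and Rpl3 were lower in the libraries labelled allo-HSCT (log2 differences -4.72, -2.75 and -0.89). Reads shared with near-identical copies are a candidate explanation, since a median of 26.6% of the lost signal, weighted by length, was found in copies of at least 95% identity, as in Rps2-ps10, which rose from 15.4 to 377 FPKM. With copies added, the log2 ratios were -1.65, -1.74 and -0.34 in place of -4.76, -2.78 and -0.89, but the copies' own signal dilutes a loss too, and 16.4% of the loss of Rps18 and 52.4% of that of Rpl3 was found in them. For Rpl29 copies as a group gained none of the loss (-8.9%). This net value cannot decide on a shift of reads to copies, as the copies moved in opposite directions. Gm8210 rose from 5.70 to 98.2 FPKM, while Gm10709 went from 84.1 to 0.17 FPKM and Gm13841 from 77.1 to 35.1 FPKM. The protein-coding gene Uimc1 (17.8 to 17.0 FPKM) was also counted among the 9 copies, over its whole length. The log2 ratio with copies added was -1.44 in place of -6.75, a change to which the copies' own signal contributes by dilution. Strain variants against the reference were not tested and stay open, as does a difference between the transplants.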
